A study of Mus musculus with 6 samples.

How the data were processed

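RNA of 6 samples of Ly6G-selected mouse bone marrow neutrophils was sequenced from Lexogen QuantSeq libraries, 3 labelled WT and 3 labelled KO for Snph, per the labels. The authors deposited one table of whole-number read counts per Ensembl gene, not scaled between samples. RSEM 1.2.3, DESeq2 and the build mm10 are named in the submitters' processing notes, with no role or order. The aligner, the annotation release, the strand setting and any filter are not given in the sources used here. RSEM divides reads that fit several genes, so counts of near-identical genes can be shared, and overlapping genes cannot be told apart without the strand setting. The libraries carry reads from the 3′ end of transcripts, so a count reflects the number of tags and not the length of the gene. Mitochondrially encoded genes were not analysed here, and no comparison table of the authors was used here.

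Columns of the table were assigned to samples by name. Groups came from the condition label and replicate numbers from the titles. Gene names, coordinates and exon overlaps were taken from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names; 51596 of 51789 identifiers had a name, and the 193 without one held 0.00812% of counts. Total counts per library ran from 7018388 to 9664381, so that 1 count was worth 0.103 to 0.142 CPM. Replicates were compared with a chi-square test of their counts over genes: the statistic per degree of freedom was 4.31 to 7.40 for the 6 pairs within groups, and no pair agreed within sampling noise. The correlation of log2 CPM was 0.969 to 0.978 for the same pairs.

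Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the deposited counts, with TMM factors, the filterByExpr filter at its defaults (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment over the 10397 genes tested, at a threshold of 0.05. All 6 libraries entered a design with the group as its one term. The standard error of a log2 fold change was computed as its size divided by the square root of the quasi-likelihood F statistic. The median standard error was 0.125 for genes with a mean of at least 10 CPM, and the common dispersion was 0.0179. Expression is given as CPM scaled by TMM factors. For Snph, counting intervals are exact binomial intervals of its count out of the total count, and a group at 0 was given a floor of 3 counts. Snph was also tested with an exact two-sided permutation test.

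The 31 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes (28 of 31) were tested with camera (limma 3.58.1) on log2 CPM. The prior count was 2 and the preset correlation 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and fry were run beside it. Fry values are of its directional test unless its mixed test, which takes change in either direction, is named. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. Lists share genes, and 16 of the 38 mature neutrophil genes belong to another list as well. The text names Snph; the 12 genes with the largest fold change in each direction among called genes with a mean of at least 10 CPM and groups that do not overlap, predicted gene models left out; the 4 members with the smallest p of each called list and of the anchoring, chemotaxis, adhesion and actin lists; the sex-linked genes; and the 2 most abundant members of each cell type list. Genes outside this rule are said to be so, and 2 genes that the rule takes are not reported here.

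Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 (RLE), upper-quartile factors, total counts only, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, leaving out each library, other thresholds, and leaving out mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes. Pseudocount alternatives apply to normalized values and were not needed. The procedure was tested on counts simulated from the means and library sizes of the 10397 genes, with 200 genes changed. For the KO-labelled against WT-labelled comparison it called 46% of genes raised 1.5-fold, 82% raised 2-fold, 90% raised 3-fold and 62% lowered to 0.5 of their level, and 11 of its 151 calls were unchanged genes. A simulated list of 30 genes raised 1.3-fold was called (camera adjusted p = 8.0e-12), and 0 of 20 unchanged lists were. Genes were drawn independently of each other in the simulation, whereas the estimated correlation in the real glycolysis list was 0.37. The simulation therefore cannot show how often correlated lists are called falsely.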

Results

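Messenger RNA was measured in neutrophils taken from mouse bone marrow with beads that bind Ly6G, a surface protein of mouse neutrophils; the labels' protocol states a purity above 95%. Libraries were made with the Lexogen QuantSeq kit, which reads a short tag from the 3′ end of polyadenylated transcripts. The 6 samples form 2 groups of 3, labelled wild type (WT) and knockout (KO) for Snph, the gene of syntaphilin, a protein that anchors mitochondria to microtubules. The series title places the work in neutrophil migration in cancer. Total counts were 7894986, 9664381 and 7018388 in WT 1, 2 and 3 and 7711877, 7179569 and 9165218 in KO 1, 2 and 3. A count was seen for 15460, 15664 and 15558 genes in WT 1, 2 and 3 and for fewer genes, 15369, 14732 and 14977, in KO 1, 2 and 3. On the first principal component (27.9% of the variance) KO 3, at -3.91, lay between KO 1 and KO 2 (23.5 and 29.2) and the WT-labelled libraries (-18.3 to -13.2). Of 51789 genes, 32130 had no count in any library and 10397 were tested, holding 99.7% of all counts. S100a8 alone took 11.99% ± 0.43 (SD, n = 3) of the counts of the WT-labelled and 13.2% ± 0.48 (SD, n = 3) of those of the KO-labelled libraries. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

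The targeted gene went against the group labels. Snph (ENSMUSG00000027457, chromosome 2, 151590549 to 151632593, minus strand, mm10) had 0 counts in each WT-labelled library and 5, 2 and 8 counts in KO 1, 2 and 3, a mean of 0.62 ± 0.30 CPM (counts per 1e6, scaled by TMM factors; SD, n = 3). Scaled to the total count alone, as for the floor and intervals that follow, the mean was 0.60 ± 0.30 CPM (SD, n = 3). A floor of 3 counts over the WT-labelled group corresponds to 0.122 CPM, and the counts of the KO-labelled group pooled in the same way to 0.624 CPM, 5.11-fold that floor. The floor bounds the WT-labelled side only, so this ratio is not a lower limit. The exact binomial 95% interval was 0.211 to 1.51 CPM in KO 1, 0.0337 to 1.01 CPM in KO 2 and 0.377 to 1.72 CPM in KO 3. Floors and intervals cover counting error only. An exact two-sided permutation test on log2(CPM + 0.1) gave p = 0.1, the smallest p that 3 against 3 samples allow. The gene lay below the filter on low counts and was not tested there; with no filter its adjusted p was 0.185 by edgeR's quasi-likelihood test. The deleted part of the gene is not given in the sources used here, so these counts do not settle the labels. A 3′ tag outside that part would be read in both groups and would not alone give this split. Every direction given for the groups rests on the labels as they stand, with the KO-labelled libraries compared with the WT-labelled ones.

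In the KO-labelled libraries, a set of transcripts known from tissue macrophages and 4 platelet markers were at about 2-fold lower levels, while 25 genes, among them stefin A and immunoglobulin genes, were higher. At an adjusted p under 0.05 (edgeR quasi-likelihood test), 107 genes differed, 82 of them lower and 25 higher in the KO-labelled libraries. The difference was at least 2-fold for 49 of the lower and 8 of the higher genes. For all 107 genes the libraries of both groups did not overlap, which held for 16.8% of all tested genes, where chance gives 10%. With scaling to the total count only, 144 genes were lower and 18 higher, a share of 88.9% lower against 76.6%, and the median of all genes moved by -0.10 on the log2 scale. DESeq2 called 174 genes (65.5% lower) and a fit with no filter on low counts called 287 (60.3% lower). Fits without WT 1, 2 or 3 made 57, 49 and 62 calls, of which 56, 47 and 56 were among the 107. Fits without KO 1, 2 or 3 made 67, 61 and 97, of which 60, 57 and 79 were among them.

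**Figure D1:**
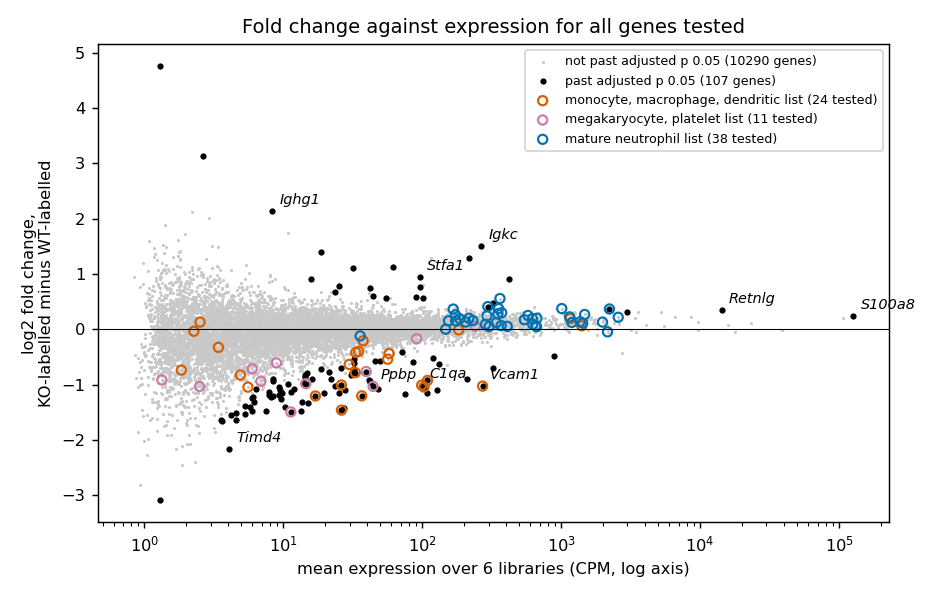
Log2 fold change of the KO-labelled against the WT-labelled libraries (vertical axis) against mean expression in CPM (horizontal, log axis) for the 10397 genes tested; black points are the 107 genes past an adjusted p of 0.05 and open circles are members of 3 gene lists. Members of the macrophage and platelet lists lie mostly below 0, and members of the mature neutrophil list lie mostly just above 0.

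Several genes known from tissue macrophages were among the 12 lower genes with the largest fold changes at a mean of at least 10 CPM. Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), which encodes a secreted protein of macrophages, fell 2.24-fold, from 104 ± 3.9 to 46.6 ± 3.6 CPM (SD, n = 3; log2 fold change -1.16, SE 0.09, adjusted p = 2.3e-05). Cd163, the scavenger receptor for haemoglobin bound to haptoglobin, fell 2.68-fold (log2 -1.42, SE 0.17) and Mrc1, the mannose receptor, 2.30-fold (-1.20, SE 0.16). Spic, a transcription factor gene required for iron-recycling macrophages, fell as well (log2 -1.21, SE 0.17). The 12 genes also included Nrgn (-1.496), the lysosomal protease gene Lgmn (-1.48), Myo10 (-1.41), Frmd4b (-1.33), Itgad (-1.32), the neonatal Fc receptor gene Fcgrt (-1.16) and Ccr3 (-1.15), the eotaxin receptor of eosinophils. Exons of Itgad overlap those of another gene on its strand, so its counts are uncertain. The adjusted p of these 12 genes was at most 0.0183, and 9 of them kept their call in every alternative tried. The call ended for Nrgn without WT 1, WT 3, KO 2 or KO 3 and with limma-voom, for Itgad without WT 2, WT 3, KO 1 or KO 2, and for Ccr3 without any library other than KO 3, with adjusted p of up to 0.1003.

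In the list of monocyte, macrophage and dendritic cell markers, 9 of 24 tested genes fell and none rose; adjusted over the list alone, 16 were lower and 1 was higher. The list median was -0.69 on the log2 scale (camera adjusted p = 2.9e-12). The variant of camera with an estimated correlation between genes did not call the list (adjusted p = 0.128), and fry gave an adjusted p of 0.0176. The complement subunit genes C1qa (log2 -1.01, SE 0.09), C1qb (-0.93, SE 0.09) and C1qc (-1.04, SE 0.10) fell together, C1qa from 132 ± 7.6 to 65.7 ± 3.2 CPM (SD, n = 3). Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), which encodes an adhesion molecule, fell from 365 ± 26.4 to 179 ± 30.6 CPM (SD, n = 3; log2 -1.03, SE 0.11, adjusted p = 0.000131). Part of the list was then divided by cell type, a division chosen after the values were seen that left out 5 tested members, among them Irf8, which fell. Of its 9 macrophage members 8 fell, with a median of -1.03. Their mean log2 level relative to the WT-labelled mean was -1.23 in KO 1, -1.06 in KO 2 and -0.82 in KO 3. None of the 6 tested monocyte members passed the test (median -0.18), nor did any of the 4 dendritic cell and MHC class II members (median -0.41), all 4 of which lay below 0. Adjusted over each part alone, 9 macrophage, 0 monocyte and 3 dendritic cell and MHC class II members were lower, and the difference between the parts was not tested. The most abundant members of the list, Ly6c2 (1377 ± 112 and 1436 ± 76.0 CPM; SD, n = 3) and Lgals3 (1087 ± 113 and 1239 ± 56.8 CPM; SD, n = 3), did not pass the test, with adjusted p of 0.836 and 0.380.

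In the megakaryocyte and platelet list 4 of 11 tested genes fell and none rose, with 5 lower when adjusted over the list alone, and the list median was -0.92 (camera adjusted p = 8.5e-07; adjusted p = 0.145 with an estimated correlation; fry adjusted p = 0.0208). Ppbp, which encodes platelet basic protein, fell from 59.5 ± 5.2 to 29.1 ± 7.2 CPM (SD, n = 3; log2 -1.03, SE 0.15, adjusted p = 0.00210). Pf4 (platelet factor 4; log2 -0.77, SE 0.16), Itga2b (the alpha chain of the platelet fibrinogen receptor; -0.99, SE 0.17) and Nrgn were the others. The call of Pf4 ended without WT 1, WT 2, KO 2 or KO 3 (adjusted p 0.167, 0.0960, 0.0867 and 0.0898), and that of Itga2b without WT 1 (0.0575). The most abundant members did not pass the test, Gp1bb at log2 0.05 (adjusted p = 0.889) and Itgb3 at -0.17 (adjusted p = 0.565). Exons of Gp1bb overlap another gene on its strand, which leaves its counts uncertain.

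**Figure D2:**
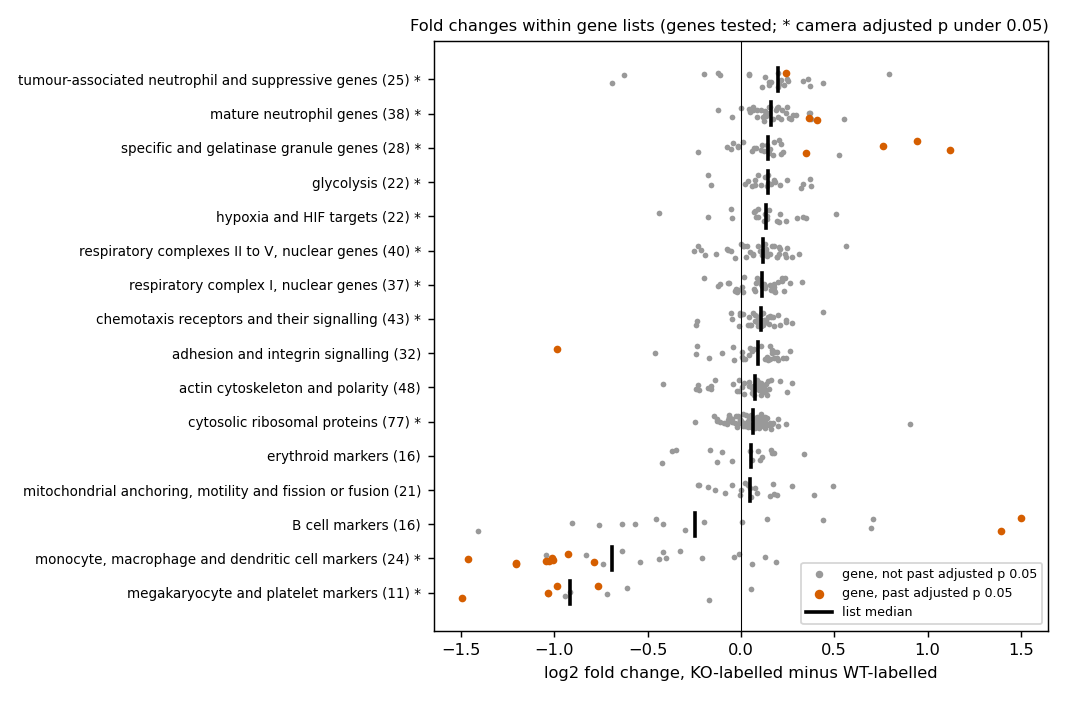
Log2 fold change of the KO-labelled against the WT-labelled libraries (horizontal axis) for each tested member of 16 gene lists (rows, number of tested genes in brackets); each point is a gene, orange where it passed an adjusted p of 0.05, and the bar is the list median. An asterisk marks the 11 lists with a camera adjusted p under 0.05, of which the macrophage and platelet lists have medians of -0.69 and -0.92.

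Among the higher genes with a mean of at least 10 CPM, predicted gene models left out, immunoglobulin genes and a cluster of stefin A genes had the largest fold changes. Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), the kappa light chain constant gene, was at 138 ± 20.7 CPM in the WT-labelled and 391 ± 233 CPM in the KO-labelled libraries (SD, n = 3; log2 1.498, SE 0.27, adjusted p = 0.0141). Igha (log2 1.29, SE 0.28) and Jchain (1.39, SE 0.30), which serve antibodies of plasma cells, rose too. KO 2 was the highest library for these genes, and without it the log2 fold changes were 0.89 for Igkc, 0.68 for Igha and 0.83 for Jchain. The stefin A genes, cysteine protease inhibitors expressed in neutrophils, were represented by Stfa2 (1.10, SE 0.22), Stfa1 (0.94, SE 0.12) and Stfa2l1 (0.76, SE 0.14). Stfa1 (ENSMUSG00000071562, chromosome 16, 36276951 to 36285373) rose from 65.6 ± 8.5 to 126 ± 22.3 CPM (SD, n = 3; adjusted p = 0.00104). These genes are near-identical copies of each other that can share reads, so the value of any single member is uncertain. Socs3, a feedback inhibitor of cytokine signalling, rose 1.67-fold (log2 0.74, SE 0.13, adjusted p = 0.0121). The remaining genes of the 12 were Tmem45a2 (0.78), Agpat4 (0.67), Sertad3 (0.59), the uridine phosphorylase gene Upp1 (0.59) and Sirpb1c (0.56), the last being a member of a gene family that can share reads. Stfa1 and Tmem45a2 kept their call in every alternative, and the other 10 lost it in at least 1 fit without 1 library, with an adjusted p of up to 0.228. Without WT 1 all of these 10 lost it. DESeq2 did not call Igkc, Igha, Jchain or Stfa2 (adjusted p 0.0893, 0.208, 0.110 and 0.103).

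**Figure D3:**
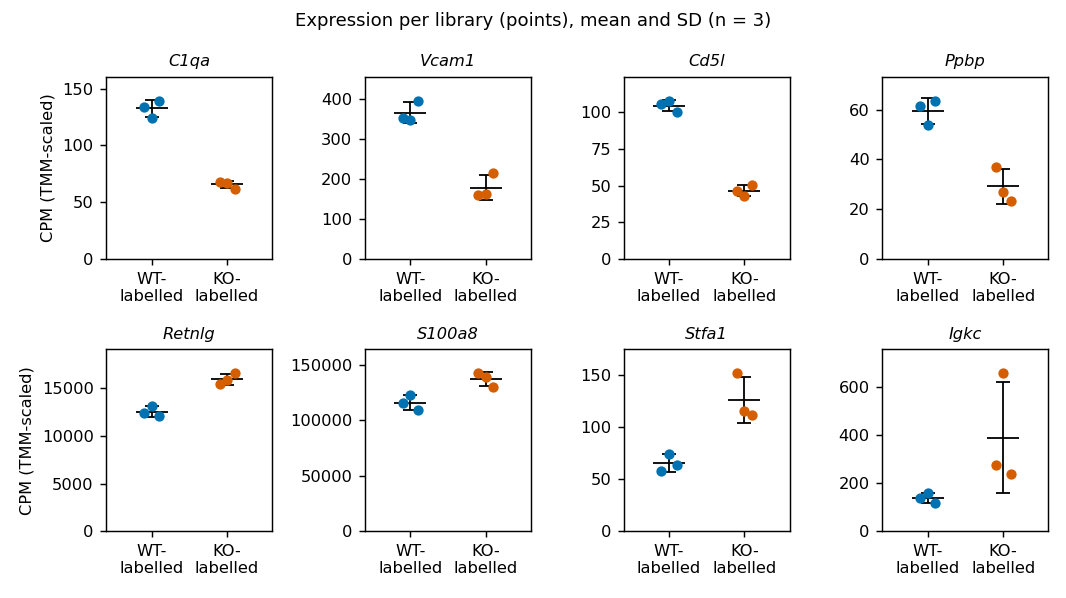
Expression in CPM (vertical axis, from 0) of 8 genes in each of the 3 WT-labelled (blue) and 3 KO-labelled (orange) libraries; points are libraries, the horizontal mark is the group mean and the bars are ± SD. Both groups are apart for each gene, and KO 2 is the library with the highest Igkc.

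The list of mature neutrophil genes was called slightly higher as a set in the KO-labelled libraries, in which the macrophage and platelet lists were called lower, and none of these 3 calls held with an estimated correlation. In the mature neutrophil list 2 of 38 tested genes rose and none fell, with 14 higher when adjusted over the list alone, and the median log2 fold change was 0.16 (camera adjusted p = 8.2e-08; adjusted p = 0.128 with an estimated correlation). Ccl6, a chemokine, rose from 1945 ± 125 to 2505 ± 38.6 CPM (SD, n = 3; log2 0.37, SE 0.07, adjusted p = 0.0126) and Ifitm2 rose by 0.41 (SE 0.09, adjusted p = 0.0487). Ifitm2 has exons that overlap another gene on its strand, which leaves its counts uncertain. Junb (0.30) and Alox5ap (0.27), needed for leukotriene synthesis, did not pass, with adjusted p of 0.0745 and 0.0801. In the list of specific and gelatinase granule genes 4 of 28 rose, with 8 higher over the list alone (median 0.14, camera adjusted p = 5.9e-05; adjusted p = 0.359 with an estimated correlation). The 4 were Retnlg, a resistin-like secreted protein, at 12553 ± 557 and 15961 ± 590 CPM (SD, n = 3; log2 0.35, SE 0.05, adjusted p = 0.00498), and the stefin genes Stfa1, Stfa2l1 and BC100530 (1.121, SE 0.11). In the list of tumour-associated neutrophil and suppressive genes 1 of 25 rose, with 7 higher over the list alone (median 0.20, camera adjusted p = 0.00252; adjusted p = 0.128 with an estimated correlation). That gene was S100a8, which forms calprotectin with S100a9, at log2 0.24 (SE 0.05, adjusted p = 0.0315); S100a9 at 0.20 (adjusted p = 0.0518), Clec4d at 0.37 (adjusted p = 0.0801) and Arg2 at 0.33 (adjusted p = 0.142) did not pass. Fry did not call the granule list (adjusted p = 0.0612) and called the mature neutrophil and tumour-associated lists (0.0208 and 0.0176). Its mixed test called the granule list (adjusted p = 0.00210) as well as the mature neutrophil and tumour-associated lists (0.000455 and 0.00222). With total-count scaling the medians of the mature neutrophil, granule and tumour-associated lists were 0.06, 0.04 and 0.09, and all 3 lists were called. The calls of Ccl6, Ifitm2 and S100a8 ended with total-count scaling (adjusted p 0.0632, 0.0970 and 0.0970). They also ended without WT 2 for Ccl6 and Ifitm2 (0.0892 and 0.116) and without KO 2 for all 3 of them (0.0526, 0.200 and 0.127), and without WT 1, WT 3 or KO 1 for Ifitm2 and S100a8 (0.145 and 0.144, 0.148 and 0.0617, 0.0828 and 0.102). Upper-quartile factors ended the calls of Ifitm2 and S100a8 (0.0627 and 0.0502), and Ifitm2 was not called without KO 3 (0.0522) or with the stricter filter (0.0532) either. Some genes gained a call: S100a9, Junb, Alox5ap, Clec4d and Arg2 with no filter (0.00442, 0.0334, 0.0263, 0.00184 and 0.0388), Junb, Alox5ap and Clec4d with DESeq2 (0.00423, 0.00784 and 0.00784), Alox5ap and S100a9 with limma-voom (0.0495 and 0.0389), S100a9 without WT 2 or KO 3 (0.0467 and 0.0312) and Clec4d without WT 3 (0.0168).

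The lists closest to the subject of the study, mitochondrial positioning and migration, held few genes that passed the test. In the list on mitochondrial anchoring, motility and fission or fusion none of 21 tested genes passed, over all genes or adjusted over the list alone, and the list was not called (median 0.05, camera adjusted p = 0.175). Without 1 library its median ran from 0.01 to 0.08. Its members with the smallest p were Dnm1l (the fission GTPase; log2 0.50, SE 0.23, adjusted p = 0.441), Pink1 (0.20, SE 0.10), Rhot1 (a motor adaptor; 0.27, SE 0.14) and Mtfr1 (0.39, SE 0.23). The list of chemotaxis receptors and their signalling was called as a set, with a median of 0.11 (camera adjusted p = 0.00128; adjusted p = 0.128 with an estimated correlation; fry adjusted p = 0.0208), although none of its 43 genes passed, alone or over all genes. Pik3r5 was at 0.28, the formyl peptide receptor gene Fpr1 at 0.24, Rgs18 at 0.21 and the complement C5a receptor gene C5ar1 at 0.20, with SE of 0.08 to 0.09 and adjusted p of at least 0.196. In the adhesion and integrin list 1 of 32 genes fell, over all genes and adjusted over the list alone, and it was the platelet gene Itga2b; Itgb1 (-0.46) and Selplg (0.20) did not pass, and the list was not called (median 0.09, adjusted p = 0.0932). None of 48 genes of the actin and polarity list passed, alone or over all genes (median 0.07, adjusted p = 0.0996). Of these, Tmsb10 was at -0.23, Was at -0.24, Cfl1 at 0.21 and Tuba1a at 0.25. Tmsb10 and Was passed as lower with total-count scaling (adjusted p 0.0421 and 0.0438), and the adhesion and actin lists were called with limma-voom (0.00740 and 0.0126). Fry's mixed test, which takes change in either direction, called the adhesion and actin lists too (adjusted p 0.000174 and 0.00292). It did not call the anchoring and chemotaxis lists (0.719 and 0.161). The medians of the anchoring, adhesion and actin lists were below 0 with total-count scaling (-0.06, -0.01 and -0.03), and that of the chemotaxis list was 0.0040. Random lists matched to the mature neutrophil list on mean expression had a median of 0.0968. No such comparison was run for the chemotaxis list, so a shift shared by genes of like abundance stays open for it.

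The lists of glycolysis, respiratory complexes, hypoxia targets and ribosomal proteins were called as sets by small shifts. No gene passed the threshold, over all genes or adjusted over the list alone. None of these lists was compared with random lists of like abundance, so a shift shared by such genes stays open. The median log2 fold change was 0.14 over 22 glycolysis genes (camera adjusted p = 0.00333; adjusted p = 0.608 with an estimated correlation), 0.11 over 37 genes of respiratory complex I (camera adjusted p = 0.00333; adjusted p = 0.421 with an estimated correlation) and 0.12 over 40 nuclear genes of complexes II to V (camera adjusted p = 0.00369; adjusted p = 0.345 with an estimated correlation). It was 0.13 over 22 hypoxia targets (camera adjusted p = 0.00864; adjusted p = 0.345 with an estimated correlation) and 0.06 over 77 cytosolic ribosomal proteins (camera adjusted p = 0.00864; adjusted p = 0.734 with an estimated correlation). Members with the smallest p were Eno1 (0.38, SE 0.14), Gapdh (0.32, SE 0.13), Slc16a3 (0.24, SE 0.08) and Pgam1 (0.18, SE 0.08) for glycolysis, Ndufs8 (0.32), Ndufa6 (0.20), Ndufa2 (0.18) and Ndufa3 (0.18) for complex I, and Atp5h (0.27), Atp5l (0.25), Cox5b (0.24) and Atp5j2 (0.19) for the other complexes. For hypoxia targets they were Higd1a (0.51), Slc2a1 (0.33), Plin2 (0.24) and Hk2 (-0.18), and for ribosomal proteins Rpl12 (0.91), Rps27a (0.24), Rps9 (0.20) and Rpl29 (0.20). Fry called none of these 5 lists (adjusted p 0.292 for glycolysis, 0.178 for complex I, 0.0612 for complexes II to V, 0.0612 for hypoxia targets and 0.377 for ribosomal proteins). Its mixed test called only that of complexes II to V (adjusted p = 0.0310). Without 1 library the medians ran from 0.09 to 0.19 for glycolysis, 0.08 to 0.12 for complex I and 0.08 to 0.13 for complexes II to V. They ran from 0.08 to 0.18 for hypoxia targets and 0.04 to 0.09 for ribosomal proteins. Eno1 ran from 0.26 to 0.53 and Gapdh from 0.16 to 0.50. With total-count scaling the medians were 0.04 for glycolysis, 0.0072 for complex I, 0.02 for complexes II to V and 0.03 for hypoxia targets; the ribosomal median was -0.04 and its call ended (adjusted p = 0.565). With no filter Eno1, Gapdh, Higd1a and Rpl12 passed (adjusted p 0.00548, 0.0321, 0.00915 and 0.0143), as did Rps27a with DESeq2 (0.0400), Higd1a without WT 2 (0.0397) and Rpl12 without KO 1 (0.0339). The ribosomal call also ended with the stricter filter (0.0687) and without WT 2 or KO 2 (adjusted p 0.0883 and 0.150), that of glycolysis without WT 3 or KO 2 (0.0825 and 0.0642), that of complex I without WT 3 (0.0624) and that of hypoxia targets without KO 3 (0.0900).

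Marker lists of the other cell types of bone marrow held few genes past the threshold and were not called by camera. Its adjusted p was 0.834 for erythroid, 0.551 for B cell, 0.551 for eosinophil, basophil and mast cell and 0.834 for stromal markers. Fry's mixed test called the B cell and eosinophil lists (adjusted p 0.00212 and 0.0120) but not the erythroid and stromal lists (0.775 and 0.376). No gene of the erythroid list passed (16 tested, median 0.05, and -0.05 with total-count scaling, -0.26 without KO 2 and -0.11 without WT 1), and Hba-a2 at 935 ± 224 and 969 ± 370 CPM and Hbb-bs at 424 ± 110 and 475 ± 166 CPM (SD, n = 3) were the most abundant. Of 16 B cell markers 2 rose, Igkc and Jchain, and Ighm was at -0.20 (adjusted p = 0.498). The B cell list median was -0.25, and from -0.42 to -0.17 without 1 library. Of 10 eosinophil, basophil and mast cell markers 1 fell, Ccr3, while Ear2 and Il6ra were both at 0.01 and the list median was -0.04, from -0.19 without WT 1 to 0.03 without WT 3. The 7 stromal and endothelial markers tested held no called gene (median 0.19, and from -0.20 without KO 1 to 0.45 without KO 3), with Pecam1 at -0.24 and Cxcl12 at 0.24. Without 1 library Pecam1 ran from -0.44 to -0.0064 and Cxcl12 from -0.0145 to 0.48. Adjusted over the list alone, these lists held 0 called erythroid genes, 2 higher and 3 lower B cell genes, 2 lower eosinophil genes and 0 stromal genes. Of T and NK cell markers only 4 could be tested and none passed; 3 of the 4 lay below 0 (median -0.65), with Cd3d at 0.27 and Cd4 at -0.80. Xist was counted in all 6 libraries, at 172 ± 3.1 and 141 ± 11.4 CPM (SD, n = 3; adjusted p = 0.154), and Ddx3y, Eif2s3y and Uty had 0 counts in all of them. Kdm5d had 1, 0 and 1 counts in the WT-labelled and 0, 0 and 3 in the KO-labelled libraries. With total-count scaling Xist passed the threshold (adjusted p = 0.0353).

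The remaining lists were not called by camera (adjusted p 0.175 to 0.834). Their medians were -0.14 for azurophil granule and promyelocyte genes, -0.05 for the cell cycle, 0.02 for the type I interferon response, -0.01 for inflammatory cytokines, 0.0010 for NADPH oxidase and antioxidant genes, -0.07 for ATF4 and the unfolded protein response, -0.03 for autophagy and lysosome, 0.11 for immediate early genes, -0.03 for the tricarboxylic acid cycle and -0.01 for genes near Snph. Single libraries moved these medians. Without 1 library they ran from -0.13 to -0.04 for the azurophil list, -0.13 to 0.02 for the cell cycle, -0.25 to 0.19 for interferon and -0.11 to 0.07 for inflammatory cytokines. They ran from -0.0098 to 0.05 for NADPH oxidase, -0.14 to -0.03 for ATF4 and -0.08 to -0.01 for autophagy. They ran from 0.0044 to 0.11 for immediate early genes, -0.10 to 0.04 for the tricarboxylic acid cycle and -0.03 to 0.01 for genes near Snph. The ATF4 list was called lower with the stricter filter (adjusted p = 0.0471). Genes past the threshold in these lists were Ctsc, Oas1a, Prdx1, Ctsb and Fkbp1a, all of them lower and named after their values were seen. Adjusted over the list alone, 1 azurophil gene was higher and 3 were lower, 1 interferon, 2 NADPH oxidase and antioxidant, 3 autophagy and 1 of the genes near Snph were lower, 1 immediate early gene was higher and 2 were lower, and 1 tricarboxylic acid cycle gene was higher and 1 lower. For the immediate early, interferon, NADPH oxidase and antioxidant, erythroid and stromal lists the median and the test, or the median and the mean, differed in sign. Over all 28 lists tested, 11 were called with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.128) and 5 by fry. Fry's mixed test called 15, among them lists that camera did not call. The azurophil, NADPH oxidase and autophagy lists were so called (adjusted p 0.00109, 0.00103 and 0.00207), the cell cycle and ATF4 lists not (0.815 and 0.0942).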

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

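Leaving members of the macrophage lists out of the count, and genes of more than 1 list out of the list tests, were alternatives chosen after seeing the data. The 107 called genes (25 higher, 82 lower) became 174 (60 higher) with DESeq2, of which 102 were shared, 162 (144 lower) with total counts only, 287 (114 higher, 173 lower) with no filter, and 182 (56 higher, 126 lower) at an adjusted p under 0.1. The larger counts with no filter came with 19659 genes tested; the cause of the others was not tested. Leaving out 1 library gave 49 to 97 calls, 11 to 29 higher and 35 to 68 lower, in fits with fewer libraries. limma-voom gave 82, RLE factors 104, upper-quartile factors 110, the stricter filter 110, a fold change of at least 1.5 gave 93 calls, leaving out the 4 gene classes gave 108, and 98 calls lay outside the macrophage lists. Of the 15 listed mitochondrially encoded genes 0 were among the genes counted, so leaving them out changed nothing. The macrophage lists could remove only 9 calls, because the second list left out genes already seen to be called. Cd5l, Cd163, Axl, Mertk, Timd4, Apoe and Fcna are therefore still among the 98, which does not separate calls related to macrophages from others. The 11 list calls became 0 with an estimated correlation and 5 with fry, ranged from 10 to 12 without 1 library, and were 12 without shared genes and 13 with limma-voom. The mean of Snph over the KO-labelled libraries stayed between 0.485 CPM (without KO 3) and 0.791 CPM (without KO 2) in every fit. Replicate numbers did not pair the samples: same-numbered libraries had correlations of -0.026, -0.00040 and -0.027 over 5935 genes, and no library correlated best with its own number. Correlations were 0.161 for WT 1 with KO 2, 0.183 for WT 2 with KO 3 and 0.193 for WT 3 with KO 1. The other pairs with unlike numbers lay from -0.206 to -0.137. A pairing under other numbers, such as a shared batch, was not fitted and stays open. With the replicate block, 92 genes were called, 84 of them shared, and 11 lists; of the named genes Agpat4 lost its call (adjusted p = 0.0519) and S100a9 gained one (0.0256). No named gene changed sign with a call. The interferon list, not called in the main comparison (median 0.02), was called upward without WT 3 (median 0.19, adjusted p = 0.0471) but downward without WT 1 (-0.15, 0.0120) and without KO 2 (-0.25, 0.00532), so single libraries decide it; without 1 library its median ran from -0.25 to 0.19. Adhesion and actin lists were called with limma-voom (adjusted p 0.00740 and 0.0126), the adhesion list also without shared genes (0.0169) and the ATF4 list with the stricter filter (0.0471). Of 630 values of named genes under settings other than leaving out a library or the block, 16 lost and 18 gained a call; of 540 without 1 library, 65 lost and 5 gained one. Small changes can be missed at this depth and number of libraries: the simulation called 46% of genes raised 1.5-fold. DESeq2 has no list test of its own and gave no list value.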

Other observations

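The erythroid comparison, the tests on Snph and its surroundings, the stefin A and plasma cell groups and the single genes in the next 2 paragraphs were chosen only after the values were seen. The stefin A genes lie side by side on chromosome 16, and 9 of the 10 could be tested. All 9 had fold changes above 0, and 5 passed the threshold. Summed over the 10 genes, which removes the sharing of reads among them, the cluster rose from 540 ± 47.9 to 1003 ± 144 CPM (SD, n = 3), 1.86-fold (log2 0.89, SE 0.10, edgeR adjusted p = 0.000269). The largest contributor was Gm5483, at 294 ± 7.5 and 552 ± 80.8 CPM (SD, n = 3). Of 11 plasma cell genes tested, 4 rose and the median was 0.76; Ighg1, an immunoglobulin heavy chain gene, had a log2 fold change of 2.13 (SE 0.33, adjusted p = 0.00420). The mean level of these genes in KO 2 stood 1.38 above the WT-labelled mean on the log2 scale, against 0.40 in KO 1 and 0.16 in KO 3, while WT 2 was at 0.19.

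Further genes known from macrophages were lower in the KO-labelled libraries. Axl and Mertk, receptors by which macrophages take up dying cells, were at log2 -1.15 (SE 0.13) and -1.08 (SE 0.12). Timd4, another such receptor, was at -2.16 (SE 0.33), and Apoe, an apolipoprotein, fell from 274 ± 13.5 to 147 ± 16.3 CPM and Fcna, ficolin A, from 176 ± 10.03 to 81.6 ± 9.3 CPM (SD, n = 3), all with an edgeR adjusted p of at most 0.00360. Gm47283, annotated on chromosome Y, had 0, 2 and 0 counts in the WT-labelled and 17, 15 and 27 in the KO-labelled libraries. Ddx3y, Eif2s3y and Uty, also on chromosome Y, had 0 counts in every library, and Xist was counted in every library. Kdm5d, on chromosome Y too, had 1, 0 and 1 counts in the WT-labelled and 0, 0 and 3 in the KO-labelled libraries. The counts of Gm47283 therefore do not show male RNA in the KO-labelled libraries, and their source was not tested.

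The macrophage transcripts that fell by about 2-fold may come from macrophages, or pieces of them, carried along with the bead-bound neutrophils, although a selection with a stated purity above 95% would remove most of them; the most abundant were Vcam1, Apoe and Fcna. A fall of every cell type other than neutrophils to the same extent is argued against by the erythroid list. Its median lay 1.08 above that of the macrophage members (95% bootstrap interval over genes 0.823 to 1.297). The interval takes genes as independent, although the estimated erythroid correlation was 0.32, and does not cover the spread between libraries. The macrophage members were split off after their values were seen, which favours a difference. The list they came from, fixed beforehand, had a median of -0.69, against 0.05 for the erythroid list. Mean erythroid log2 levels relative to the WT-labelled mean were -0.26, 0.32 and -0.19 in KO 1, 2 and 3. The difference from the macrophage members was smallest of the 6 fits without 1 library when KO 2 was left out. It was then 0.774 (0.581 to 0.903), with an erythroid median of -0.26. A fall of differing size stays open. Medians also lay below 0 for platelet (-0.92), the 4 tested T and NK cell (-0.65), dendritic cell and MHC class II (-0.41), B cell (-0.25), monocyte (-0.18) and eosinophil (-0.04) markers. The stromal median was 0.19. A lower amount of macrophage RNA alone stays open: a second list of 20 tested macrophage genes had a median of -0.47 with 75% below 0, but it left out genes already seen to be called, which pulls its median towards 0, so it does not decide. Fewer macrophage fragments and a different state of the macrophages therefore cannot be told apart, because no measure of cell numbers was used here, nor how many of these genes neutrophils express. An effect of the Snph genotype stays open and untested, as does a difference in the isolation of the samples.

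The mature neutrophil list was higher by a median of 0.16 (95% bootstrap interval over genes 0.125 to 0.218). On the TMM scale its mean level was above that of every WT-labelled library in each of the 3 KO-labelled libraries. The TMM factors were 1.015 to 1.061 in the WT-labelled and 0.949 to 0.980 in the KO-labelled libraries, so this separation rests on that scaling. With total-count scaling the list median was 0.06. Loss of RNA from the totals is argued against for the genes called lower, since the RNA missing from them could raise the rest by only 0.00313. That value was taken on the TMM scale and leaves out macrophage genes that were not called, so it is not an upper limit. A trend of fold change with abundance is argued against as the whole cause, since the median lay at the 99.99 percentile of 10000 random lists matched on mean expression, whose own median was 0.0968 and whose central 95% ended at 0.136. Part of the shift is therefore shared by genes of like abundance, and no other list was compared in this way. Camera with an estimated correlation, 0.054 for this list, did not call it. The size of that correlation need not be the reason. The chemotaxis and tumour-associated lists had estimates of 0.0063 and -0.018, below the preset 0.01, and lost their calls too. A higher share of mature cells and an effect of genotype were not tested.

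The Snph reads lie in the libraries labelled KO. Counting noise at equal levels is argued against by 15 counts against 0 (exact binomial p = 2.6e-05, which compares these libraries and not the genotypes). The count was higher in the KO-labelled library in 9 of 9 pairs, which restates the reads that raised the question of exchanged group labels and is no test of it; an exchange and a targeted allele that yields more 3′ tags than the intact gene, which an intact 3′ end alone would not give, cannot be told apart here. A changed segment of chromosome 2, such as DNA carried along with a targeted allele, stays open: 3 of 125 tested genes within 10 Mb were called against 104 of 10272 elsewhere (odds ratio 2.40, 95% interval 0.481 to 7.39, Fisher's exact p = 0.138). They included Snx5 and Fkbp1a, the gene at 151542483 to 151561692 on chromosome 2, separated from Snph by Sdcbp2, which was too low to test; Fkbp1a fell from 8.83 ± 2.3 to 3.16 ± 0.50 CPM (SD, n = 3; log2 -1.47, SE 0.27, edgeR adjusted p = 0.0161).

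The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10, the labelled one, called as many as 107 genes, and the highest other called 13. Likewise 1 of 10 called as many as 11 lists, and the highest other called 9.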
